A study of Homo sapiens with 4 samples.

How the data were processed

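5-Hydroxymethylcytosine (5hmC), the first product of the oxidation of 5-methylcytosine by the TET enzymes, was profiled in genomic DNA from 3 medulloblastomas, malignant tumours of the cerebellum, and from 1 normal brain. The assay was hMe-Seal, in which a glucosyltransferase places a modified glucose on 5hmC so that the DNA fragments that carry it can be tagged with biotin and captured. Per the labels' protocols, libraries were built from 25 ng of DNA, fragments of 150 to 300 bp were selected, and 38 cycles were sequenced from one end on an Illumina instrument.

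The deposited file of each library was a list of called regions on build hg19, each with chromosome, start, end and a score, called for each library and not on pooled samples. CASAVA 1.4, Bowtie 0.12.9 and MACS 1.4.2 are named in the submitters' processing notes. The calling threshold, the treatment of duplicate reads and the use of an input library as background are not given in the sources used here. The score that the authors deposited was 50 or more in every library, and its form was that of the scaled negative log10 p that this peak caller writes by default, a scale the files do not state. It was used only to rank and filter regions within a list.

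Read depth is unknown, because the lists hold no read counts, so no interval or floor based on depth was set on a region. A region missing from a list means that it did not reach the caller's threshold in that library, which a shallower or less enriched library also produces. The DNA copy number of the samples was not measured in these lists and also changes the chance of a call. The number of libraries therefore limits the precision: with 3 tumours against 1 normal sample the smallest exact permutation p is 0.25, and no p-value is given between the groups. The labels do not name the brain region of the normal sample. Donor and brain region may therefore differ along with tumour status, and their effects cannot be told apart.

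Positions on the 22 autosomes were analysed. The sex chromosomes were not analysed, since the samples are tissue from donors. Within a list no regions overlapped (0 cases). Regions of the 4 libraries were merged where they overlapped by at least 1 bp, and each merged region was assigned the set of libraries in which it was called. A merged region called in all 3 tumours and not in the normal is named tumour-common, and one called in the normal and in no tumour is named normal-only. Because 1 library stood alone on one side, each of the 4 libraries was also set in turn against the other 3, so that the counts for the normal could be read beside the counts for each tumour. Overlap of 2 libraries was measured as the Jaccard index, the base pairs called in both divided by the base pairs called in either. The overlap that chance gives was taken from 100 random circular shifts of each library's regions within the stretch of each chromosome that held called regions.

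The rule for named regions, fixed before the data were examined like the tests and alternatives except those named as later, took the 10 tumour-common and the 10 normal-only regions with the most base pairs. Gene annotation and sequence of build hg19 were not used here, and a gene table of another build was not joined to these positions. The planned comparisons of gene features, sequence composition, covered share per gene and 16 lists of genes were therefore not made, and regions are named by position alone.

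The alternatives were lists cut to the 69049 best-scoring regions of each library, the regions of each library that scored at or above its median, an overlap of at least 50% of the shorter region, absence defined as no region within 1 kb, merging of regions within 500 bp, counting in base pairs, and leaving out each tumour. The shares by chromosome and near the q-arm ends, and the alternatives that leave out chromosomes or use equal numbers of regions per chromosome, were chosen after the data were seen. So were the ranking by base pairs called in all 3 tumours and the stretches examined on chromosomes 10 and 19. The search for stretches called in a single library and the measures over bins of 1 Mb were also later choices. Values of the tumours are given by chromosome as mean, SD and range, not by donor. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The interval functions were tested on 44000 simulated regions, and the number recovered for each set of libraries equalled the number planted. The planted sites lay far apart, so the merging of chains of neighbouring regions was not tested.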

Results

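The study asked where 5hmC differed between medulloblastoma and normal brain, and which of the differing regions the tumours had in common. It comprised 3 tumour libraries and 1 normal library. On the autosomes, 87161 regions were called in tumour 1, 70159 in tumour 2, 71703 in tumour 3 and 69049 in the normal. The tumours averaged 158 Mb of covered sequence (SD 14.5, n = 3), against 141 Mb in the normal, a ratio of 1.12 ± 0.10 (SD). The covered part was 5.68% ± 0.52 (SD, n = 3) of the stretch of autosomes that held called regions in the tumours and 5.07% in the normal. Regions had a median width of 1599 bp ± 83.2 (SD, n = 3) in the tumours and 1540 bp in the normal. Those wider than 10 kb numbered 463 ± 40.3 (SD, n = 3) in the tumours and 431 in the normal. For the median width and the number of wide regions the difference was smaller than the spread between tumours. For covered sequence it exceeded 1 SD of the tumours, and all 3 tumours lay above the normal.

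The tumours were on average more similar to each other than to the normal brain, but by less than the spread between pairs. The Jaccard index averaged 0.343 ± 0.029 (SD, 3 pairs) between tumours and 0.318 ± 0.038 (SD, 3 pairs) between a tumour and the normal, and the ranges overlapped. The highest of the 6 values, 0.370, was that of tumours 2 and 3. The next, 0.361, was that of tumour 2 with the normal. The lowest, 0.289, was that of tumour 1 with the normal. Pairs that share a library are not independent, and their SD ignores this. Read tumour by tumour, the normal was the least similar library for tumour 1 and for tumour 3 (0.304). Tumour 2 was closer to the normal than to tumour 1 (0.346). Regions shifted at random gave 0.035 on average and 0.051 at most, so each pair shared far more sequence than chance placement gives. When each library in turn was set against the other 3, the mean within the 3 exceeded the mean with the library set apart by 0.025 for the normal and by 0.029 for tumour 1. By this measure the normal did not stand farthest from the rest on the full lists. Tumour 1 had the longest list (87161 regions), and unequal lengths can lower the index. Values with a tumour set apart are not given for lists of equal length, so an effect of list length on this order stays open.

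**Figure D1:**
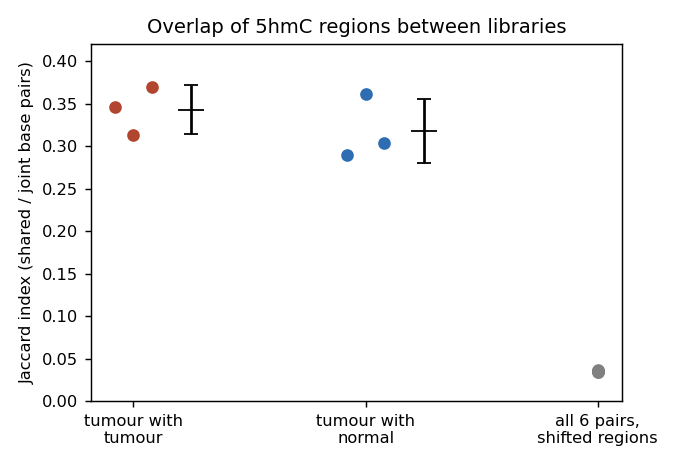
Overlap of called 5hmC regions, as Jaccard index (shared over joint base pairs), for the 3 pairs of tumours, the 3 pairs of a tumour with the normal, and the means of all 6 pairs after circular shifts; black bars are mean ± SD over pairs. The tumour pairs (0.313 to 0.370) and the tumour-normal pairs (0.289 to 0.361) overlap, and both lie far above the shifted regions.

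Merging the 4 lists gave 140356 regions. A core of 16344 regions (11.6%) was called in all 4 libraries. Their median width was 4521 bp, and they held 30.3% of the merged sequence and would number 389 by chance placement. That sequence counts every base of a merged region, and 38.7 Mb of its 98.3 Mb was called in all 4 libraries. Merged regions grow wider with the number of libraries they join, and those called in 1 library had medians of 1208 to 1294 bp. Of the sets of regions defined by the libraries that shared them, the core had the highest median score in each list, at percentile 67.3 of the normal's list and between 73.2 and 75.4 in the tumours' lists. Most of the merged regions, 77826 (55.4%), were called in a single library, with a median score percentile between 27.1 and 31.8.

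Tumour-common regions numbered 6260 and covered 17.6 Mb. Their median width was 2400 bp, against 2519 to 2942 bp for the other sets of regions called in 3 libraries. They made up 27.7% of the 22604 regions called in all 3 tumours. Their median score percentile was 60.3, 46.6 and 53.3 in tumours 1, 2 and 3. When a tumour took the normal's place, the regions called in the remaining 3 libraries and missing from it numbered 3913 for tumour 1, 2941 for tumour 2 and 4590 for tumour 3. The normal thus gave the highest of the 4 counts. No p-value below 0.25 can come from 4 such choices, and with lists of equal length the count for the normal was 5318 against at most 4718 for a tumour.

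Normal-only regions numbered 16971 and covered 23.8 Mb. Their median width was 1209 bp, against 1208 to 1294 bp for regions called in a single tumour. They made up 30.2% of the regions called in the normal. The remaining 69.8% were called in at least 1 tumour. Regions called in a single tumour numbered 30230, 13162 and 17463 in tumours 1, 2 and 3, so the count for the normal lay within the range of the tumours. With tumour 2 left out, the normal (21973) lay below both remaining tumours, the lower of which gave 22999. The normal-only regions had a median score percentile of 31.5, and regions private to 1 tumour had 27.1 to 31.8.

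**Figure D2:**
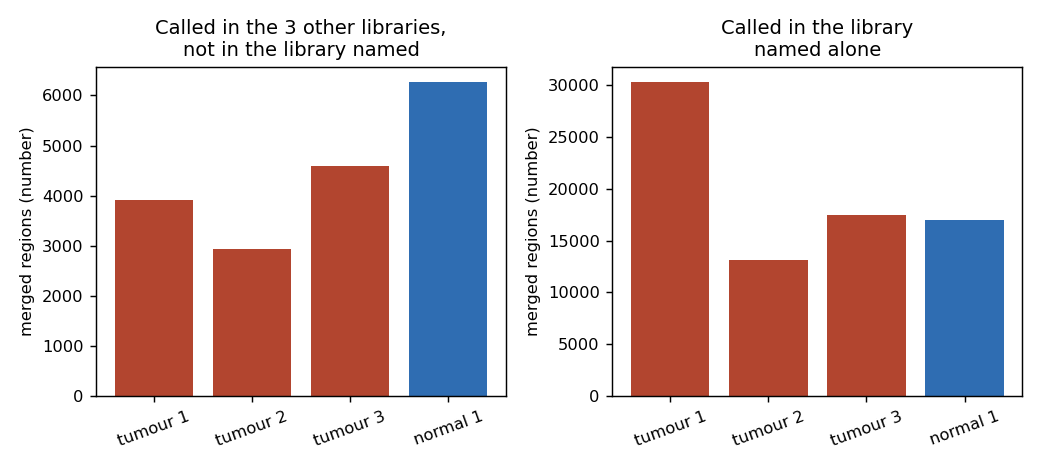
Number of merged regions called in the 3 other libraries and missing from the library named (left), and called in the library named alone (right), for tumours 1 to 3 and the normal; axes start at 0 and differ between the panels. The normal has the highest count on the left (6260) and lies within the range of the tumours on the right (16971 against 13162 to 30230).

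Chromosome 19, one of the most gene-dense chromosomes, had the largest share of normal-only regions. Of its 5133 merged regions, 1416 (27.6%, exact binomial 95% interval 26.4 to 28.8, which covers counting error alone) were normal-only, against 12.1% over all autosomes. Regions private to 1 tumour made up 3.14% to 12.1% of the merged regions of chromosome 19. Shares of this size were not limited to the normal, since regions private to 1 tumour reached 45.3% on chromosome 2, 33.7% on chromosome 4 and 30.3% on chromosome 15. It held 6.27% of the normal's regions and 3.81% ± 0.98 (SD, n = 3) of the tumours'. Chromosomes 16, 21 and 22 also held a smaller share in each of the 3 tumours than in the normal. Chromosomes 2, 3, 4, 5, 12, 13, 15 and 18 held a larger share in each tumour. Chromosome 3 held 5.75% ± 0.06 (SD, n = 3) of the tumours' regions and 4.93% of the normal's. Chromosome 18 held 2.81% ± 0.03 (SD, n = 3) and 2.46%. On these 12 of 22 chromosomes the normal lay outside the tumours, where chance gives 11, so their number alone sets the normal apart no more than chance does. Tumour-common regions were most frequent on chromosome 20 (6.20% of its merged regions) and least frequent on chromosomes 6 (0.73%) and 8 (0.98%). On the last pair the highest and lowest tumour shares of regions differed by the largest factors, 6.76 and 3.57, and the sequence covered was between 0.20 and 1.42 times the normal's on chromosome 6 and between 0.27 and 1.11 times on chromosome 8.

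**Figure D3:**
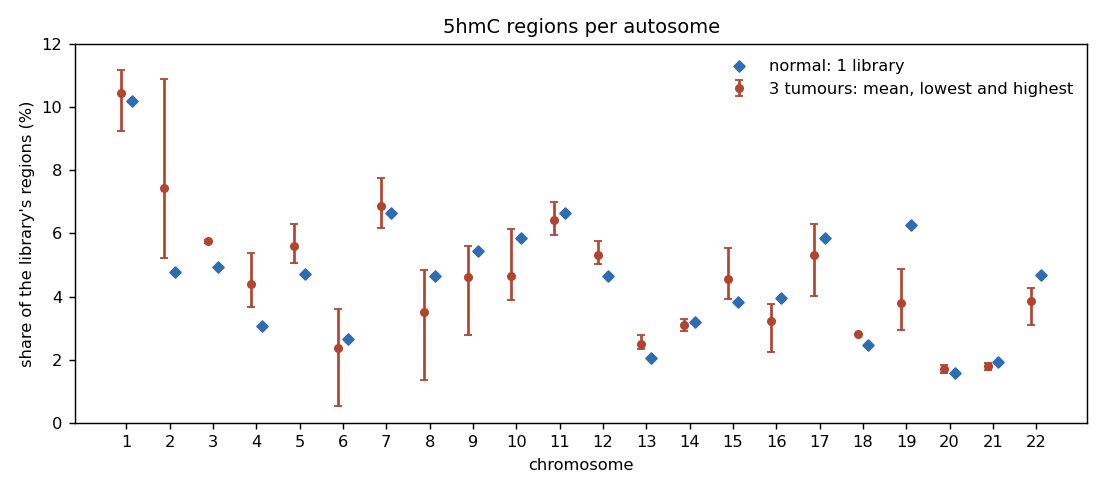
Share of each library's called regions on each autosome, in percent; circles and bars are the mean, lowest and highest of the 3 tumours and diamonds are the single normal library. Chromosome 19 holds 6.27% of the normal's regions, above all 3 tumours, and chromosomes 2, 6 and 8 show the widest ranges among tumours.

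A larger share of the normal's regions lay near the end of the long (q) arm. Shares near the opposite ends of the chromosomes are not given, so the excess cannot be called particular to the q arm. Within 5 Mb of the last called position of that arm lay 16.4% of the normal's regions and 11.3% ± 1.18 (SD, n = 3) of the tumours', with a highest tumour value of 12.6%. The normal exceeded all 3 tumours on 19 of 22 chromosomes, where chance gives 5.5, and no tumour exceeded the other 3 libraries on more than 1. The 22 chromosomes come from the same libraries and are not independent, so this count cannot be read as 22 separate trials. With the library as the unit, 1 normal against 3 tumours gives no exact permutation p below 0.25. The difference was large on chromosome 13, with 35.5% in the normal and 19.9% ± 2.50 (SD, n = 3) in the tumours. On chromosome 18 the shares were 20.9% and 11.3% ± 2.41 (SD, n = 3). Among merged regions, 12.96% of the normal-only, 6.10% of the tumour-common and 16.5% of the core regions lay in these end stretches.

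**Figure D4:**
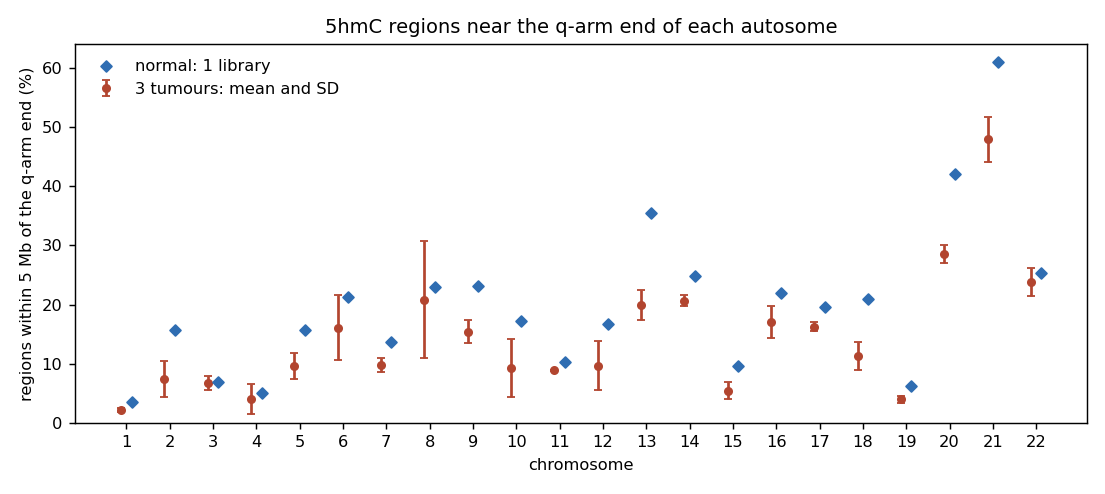
Percent of called regions of each autosome that lie within 5 Mb of the last called position of the q arm; circles and bars are mean ± SD of the 3 tumours and diamonds are the normal library. The normal lies above all 3 tumours on 19 of 22 chromosomes, with the largest gap on chromosome 13 (35.5% against 19.9%).

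The 10 widest tumour-common regions were 13938 to 28340 bp wide and lay on chromosomes 3, 5, 12, 17, 19 and 22 (hg19). These widths join the calls of 3 libraries and are not comparable with those of regions called in a single library. The region on chromosome 5, positions 139040349 to 139059267, was covered over 16536 bp ± 2426 (SD, n = 3) in the tumours. The region on chromosome 22, positions 49094294 to 49111302, was covered over 14429 bp ± 3238 (SD, n = 3). A pair of neighbouring regions lay on chromosome 19, at 13137368 to 13152828 and at 13159491 to 13173428. Over the 36.1 kb from the first to the last base of this pair, the tumours had 30.2 kb ± 5.60 (SD, n = 3) under called regions and the normal had 1.32 kb. The pair holds no call of the normal by definition, so calls of the normal could lie only in the gap between its members. The regions at 70932288 to 70946546 on chromosome 17 and 194084480 to 194098533 on chromosome 3 were covered over 10563 bp ± 3964 and 10141 bp ± 4656 (SD, n = 3). The remaining 4 lay on chromosome 12, the widest at 3000549 to 3028888, where the tumours differed greatly, with 2873 to 28340 bp covered. When regions were ranked by the base pairs called in all 3 tumours, the regions on chromosomes 5, 19 (the first of the pair) and 22 came first, with 13467, 10951 and 10649 bp, and none of the first 10 lay on chromosome 12.

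Of the 10 widest normal-only regions, 7884 to 15488 bp wide, 6 lay close together near the end of the long arm of chromosome 10. They fell within 175 kb, from 134855561 to 135030698. The normal had 28 called regions over 129 kb of this stretch, and the tumours had 0 kb. The stretch was bounded by the 6 regions, which hold no tumour call by definition. Tumour calls could have lain only in the sequence outside these regions. The widest of them, at 134989229 to 135004716, scored at percentile 94.97 of the normal's list, and the region at 134939436 to 134947812 at percentile 99.99. In the 1 Mb just before the stretch, the normal had 708 kb under called regions and the tumours 235 kb ± 139 (SD, n = 3). The other 4 lay on chromosome 1 at 2791769 to 2803276, on chromosome 16 at 89955544 to 89964150, and on chromosome 17 at 73614806 to 73623855 and 7223552 to 7231435. Their scores in the normal lay at percentiles 99.9, 95.02, 73.9 and 99.1 of its list.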

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

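The ratio of covered sequence (1.12) was 1.06 to 1.16 over its 5 alternatives. It was lowest with lists of equal length (1.056) and without tumour 1 (1.062). The excess of overlap between tumours (0.025) was 0.017 to 0.037 over 5 and kept its sign. Both moved by less than 1 SD, but the SD of the overlap (0.029) is larger than the excess itself. A shift below 1 SD therefore does not show that the excess is stable. The tumour-common count stayed the highest of the choices of library under each alternative run (4 choices, or 3 where a tumour was left out). With the regions that scored at or above their library's median, which shortens the lists by construction, it was 3128 (a tumour gave at most 2379) and the normal-only count was 8426. Without the 8 chromosomes on which the tumours' shares differed over 1.5-fold, an alternative chosen after seeing the data, the normal-only count was 9611, the fewer chromosomes lowering it by construction, and the tumour-common count was 4615. Without 1 tumour the tumour-common count was 11496 to 12792, 11496 without tumour 1, 12792 without tumour 2 and 12717 without tumour 3, since a region then had to be called in fewer libraries. The normal-only count was 20867 to 22537 without 1 tumour, within the range of the remaining tumours except without tumour 2, where it was 21973 against 22999 for the lower tumour. Counted as bases called in 1 library alone, which include bases inside merged regions shared with others, the normal had 36.7 Mb, below 58.2 Mb for tumour 1 and above 36.0 Mb for tumour 3. By the length of the single-library regions themselves tumour 3 (24.1 Mb) stayed above the normal (23.8 Mb), as it did by count, so the swap came with the bases inside shared regions. The normal-only share of chromosome 19 was 28.0% to 39.2% over its 5 alternatives, the highest without tumour 3. The excess of the normal near q-arm ends was 2.87 to 6.30 percentage points over its 10 alternatives. The lowest was within 2 Mb of the end, where the shares themselves were smaller, 7.44% in the normal and 4.57% in the tumours. Alternatives for gene features, sequence composition and gene lists were not run, since annotation and sequence of build hg19 were not used here. No paired analysis was possible because the groups shared 1 replicate number. Read depth is unknown, so a missing call does not show an absence of 5hmC.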

Other observations

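Of the stretches free of tumour regions, the one near the end of chromosome 10 held the most sequence called in the normal, though others were longer or held more regions. No tumour region lay between positions 134836223 and 135071322 (hg19), and 42 regions covered 171 kb of these 235 kb in the normal. In the same search the next stretches for the normal lay on chromosome 5, positions 1952044 to 2989367, with 92.8 kb covered by 65 regions, and on chromosome 19, positions 29134487 to 29866288, with 57.0 kb covered. For the tumours the most that one library covered in a stretch free of calls in the other 3 was 61.0 to 72.4 kb. Stretches with 50 kb or more numbered 4 for the normal and 1 to 2 for each tumour. The normal's covered sequence was also packed into fewer places: its Gini index over bins of 1 Mb was 0.760, against 0.674 ± 0.047 (SD, n = 3) in the tumours, and 21.04% of the bins held none of its regions, against 12.8% ± 6.03 (SD, n = 3). The highest tumour values were 0.713 and 19.4%. These differences were 1.85 and 1.37 tumour SD, and 2.38 and 1.37 with lists of equal length.

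Of the tests below, those on the q-arm ends were chosen after the results were seen, as was the ratio used for the second pattern, whose choices of library and equal list lengths were fixed before. The values argue against differences in list length as the whole cause of the normal's larger share of regions near the q-arm ends. With equal numbers of best-scoring regions the normal exceeded the tumour mean by 4.77 percentage points, with an SD of 0.94 among tumours. The cut removed few regions from tumours 2 and 3, with 70159 and 71703 in full against the normal's 69049. Equal length does not make read depth or enrichment equal. Differences in the number of calls on whole chromosomes were also argued against: with the same number of best-scoring regions taken from each chromosome in the 4 libraries, the normal still lay above all 3 tumours on 19 of 22 chromosomes, and no tumour stood above the other libraries on more than 2. Read depth, the strength of enrichment, partial gains or losses of chromosome arms, and recovery of fragments that depends on GC content remain open, as none was measured. No biological explanation was tested. With 1 normal library of an unnamed brain region, tumour, region and donor may each account for the difference.

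The second pattern is that the normal was missing from more regions called in the other 3 libraries than any tumour was, 6260 against at most 4590. Of the 4 choices of the library set apart, only the normal gave a count this large, and 4 choices are too few for a share under 0.05. List length stays open in part: with equal lengths the ratio to the highest tumour count was 1.13, between no excess and the 1.36 of the full lists, and there is no replicate normal to give its spread. The difference between tumour and normal tissue stays open as well, untested.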
